A study of Homo sapiens with 43 samples.

How the data were processed

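The series applied methyl-CpG-binding domain (MBD) capture followed by sequencing to DNA inputs from 1 ng to 1000 ng. MBD capture uses the methyl-binding part of a protein, held on magnetic beads, to pull down double-stranded DNA fragments that carry methylated CpG dinucleotides, and the captured fragments are sequenced. Samples were grouped from their titles and from the characteristics given for them, which list the DNA input, the methylation and amount of the filler DNA, the MBD protein, the beads, the wash and the elution. Each of the 43 libraries received a group in this way. Per the labels' protocols, DNA was extracted with QIAamp kits for circulating nucleic acid and for blood, and libraries were made with the KAPA Hyper Prep kit.

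Per the submitters' processing notes, the tools named were Bowtie2 2.4.2, SAMtools 1.11, R 4.0.3 and bedtools 2.28.0, and the genome build was hg19. The role and order of those tools, the treatment of duplicate reads and the filters on mapping quality are not given in the sources used here. The authors deposited 1 table of coverage per annotated region and 3 tables of coverage summed per CpG class, and by their file names the values are in TPM, a unit that divides coverage by the length of each region and then scales each library to a fixed total.

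No library value was analysed here. The 43 library columns of the region table carry a prefix and a number as names, and the numbers are not consecutive. Of these names, 0 occur in a title, a description or another label of a sample. The 3 tables of class sums name libraries by row. The table named for cfMBD holds 43 rows, a table named for cfMeDIP holds 24 rows and a table named for MBD holds 4 rows, and the latter tables are named in no label of the 43 samples. None of the 71 row names occurs in a sample label. Matching columns to samples by their order or by their values would have been a guess, so these columns and rows were left out of every step. A summary workbook that the sample descriptions name, and the names under which the reads were archived, were not used here. The depth of each library was therefore not assessed, and no replicate spread, interval or test of a group difference is given.

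The region annotation itself belongs to no library and was analysed. For each region it gives a chromosome, a first and last base, a length, a name and a CpG class (island, shore, shelf or inter). Class sizes, lengths, neighbours and chromosome densities were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and the plots were drawn with matplotlib 3.10.9. Coordinates are on hg19 and count from 1. Gene names were not assigned to regions, because the gene table at hand is on another genome build and coordinates were not converted between builds. The class, length and neighbour summaries were tested on a simulated tiling of known class sizes before use. That tiling held no gap or overlap, and the chromosome densities were not tested in this way. Values of the annotation are complete counts of a fixed list, so they carry no sampling error.

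Before the data were examined, 29 results with tests and 117 alternative settings were fixed. They covered regions that differ in log2(TPM + 1) by limma and the share of TPM in CpG islands by exact permutation tests. None of them was computed, since each needs libraries assigned to groups. The rule for the regions named in the text (largest changes past the threshold) was not used for the same reason. The 6 gene lists fixed with it (colorectal cancer methylation markers, imprinted regions, germline, housekeeping, blood cell, and epithelial and colon genes) were not used because they also need genes placed on hg19. Regions named here were chosen instead as the 3 longest islands and the 3 longest inter regions on autosomes, a rule set after the annotation had been seen.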

Results

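The series comprised 43 MBD capture libraries in 27 groups, of which 35 were made from pooled plasma of healthy people and 8 from HCT116, an established human colorectal carcinoma cell line. Of the groups, 16 held 1 library, 6 held 2 libraries and 5 held 3 libraries. Cell-free DNA circulates in plasma as short fragments and in small amounts, and the plasma libraries each started from 3 ng. Filler DNA was added to bring up the amount of DNA in the capture reaction.

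The first set of conditions varied the MBD protein and the beads at 97 ng of fully methylated filler. Protein and beads were set at 2 µg with 30 µl (3 libraries), at 2 µg with 3 µl (3 libraries) and at 0.2 µg with 30 µl (3 libraries). These libraries had a standard wash and a single high-salt elution. The combination of 0.2 µg and 3 µl with this filler was represented, at that wash and elution, by 1 library. The second set varied the methylation of the filler at 0.2 µg of protein and 3 µl of beads, with 3 libraries on unmethylated filler and 3 on filler that was 50% methylated. The libraries of the second set also had a standard wash and a single high-salt elution. Fully methylated filler with these amounts, at that wash and elution, rests on the 1 library named above. The third set crossed 2 washes, standard and double, with 8 elution conditions per wash, giving 16 libraries with 1 per condition. These 16 libraries shared 0.2 µg of protein, 3 µl of beads and 97 ng of fully methylated filler, and include the single library of the first set with these amounts. The elutions differed in salt level and in whether the captured DNA was released in a single step or in successive fractions. Each wash had single elutions at low, medium and high salt, and multiple elutions at low, medium and high salt. The remaining conditions were labelled multiple medium+high and multiple low+medium+high. Libraries of these combined conditions may be pools of the other fractions, so they cannot be assumed to be independent of them. The fourth set raised the DNA in the reaction to 500 ng (497 ng of filler, 1 µg of protein, 15 µl of beads) and to 1000 ng (997 ng of filler, 2 µg of protein, 30 µl of beads), with 2 libraries each. Within this set the filler was fully methylated, and the protein and the beads rose with its amount. The wash was standard and the elution was a single high-salt step. The libraries with 997 ng of filler shared their 2 µg of protein and 30 µl of beads with the 3 libraries of the first set that had 97 ng of filler.

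The HCT116 libraries formed an input series of 1, 10, 100 and 1000 ng with 2 libraries at each input. Fully methylated filler of 99 ng and 90 ng was added at 1 ng and 10 ng, and none at 100 ng and 1000 ng. The 3 lower inputs shared 0.2 µg of protein and 3 µl of beads, whereas 1000 ng was captured with 2 µg and 30 µl, so that step of the series changed the input and the reagents together.

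The comparisons that this design implies, between protein and bead amounts, fillers, washes, salt levels, DNA totals, HCT116 inputs, and HCT116 and plasma, were not made. The names of the 43 library columns match none of the sample labels used here, and no library value is reported.

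Coverage had been summarised over 144965 regions of hg19, which were split into 4 CpG classes. CpG islands are short stretches rich in CpG dinucleotides that often lie at gene promoters, shores and shelves are the successive flanks of an island, and inter regions are the remainder, assembly gaps included. Shores were the most numerous class, with 51914 regions or 35.8% of the total. Shelves followed with 43747 regions (30.2%), islands with 28691 (19.8%) and inter regions with 20613 (14.2%). The order by length was different. Inter regions held 93.3% of the annotated bases, shores 3.25%, shelves 2.77% and islands 0.696%. Islands, shores and shelves together made up 85.8% of the regions and 6.72% of the bases.

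**Figure D1:**
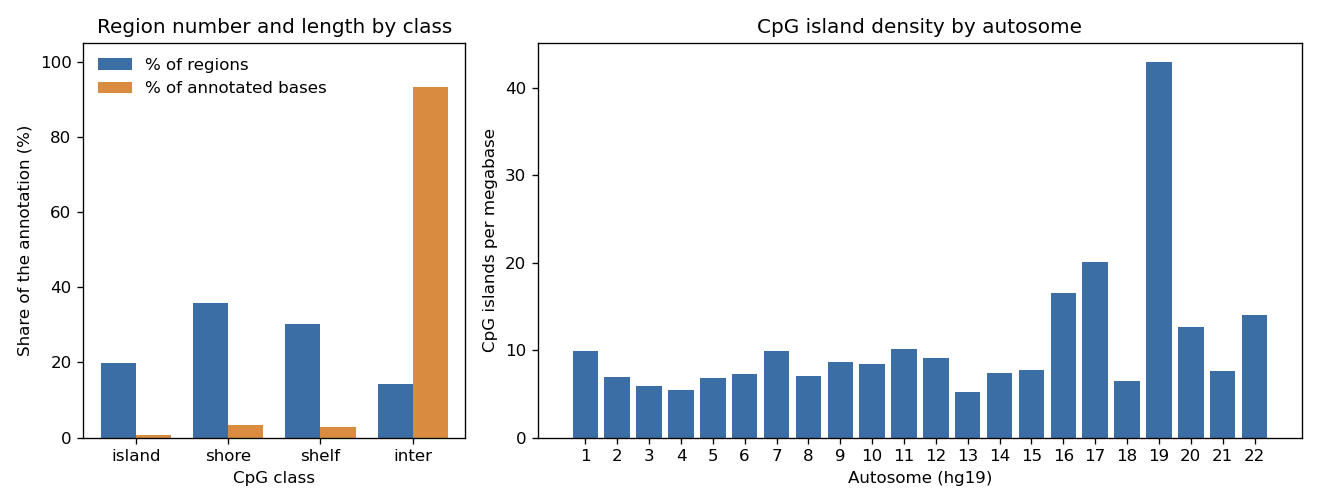
Left, the percent of regions and the percent of annotated bases (vertical axis) in each CpG class, drawn as paired bars. Right, the number of CpG islands per megabase (vertical axis) on each of the 22 autosomes of hg19, with unsequenced bases counted. Islands were 19.8% of regions but 0.696% of bases, and chromosome 19 stood highest with 43.0 islands per megabase.

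The islands had a median length of 559 bases, with quartiles at 323 and 942 bases, and the shortest spanned 201 bases. Of the islands, 12826 (44.7%) were shorter than 500 bases and 1257 (4.38%) were longer than 2000 bases. Shores measured exactly 2000 bases in 46440 cases (89.5%), were shorter in 3419 and longer in 2055. Shelves measured exactly 2000 bases in 41054 cases (93.8%), were shorter in 1534 and longer in 1159. Inter regions had a median length of 43272 bases, 77.4 times that of the islands, and the longest spanned 30432250 bases. This longest region lay on a sex chromosome, and assembly gaps count towards the length of inter regions.

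The regions tiled each sequence without a break. None of the 144872 pairs of neighbouring regions on a sequence overlapped or left a gap. An island bordered a shore in 57382 pairs, a shore bordered a shelf in 46439 pairs and a shelf bordered an inter region in 41051 pairs. No other pair of classes was adjacent.

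TPM divides by length, so a library with the same coverage per base everywhere would have the same TPM in each region. The class totals of such a library would follow the number of regions and not the number of bases, which places 19.8% of its TPM in islands although islands hold 0.696% of the annotated bases. This reference level follows from the annotation, the unit and the assumption of even coverage. Unsequenced bases can carry no coverage, and how reads were counted per region is not given in the sources used here. The level was not compared with any library.

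Island density differed widely between the autosomes. Densities were taken over every base of the hg19 sequence, so unsequenced stretches of the assembly count as bases. Chromosome 19 carried 2541 islands at 43.0 per megabase, the highest density, and these islands were short, with a median of 450 bases. Chromosome 17 followed with 1634 islands at 20.1 per megabase. Chromosome 13 had 605 islands at 5.25 per megabase and chromosome 4 had 1031 islands at 5.39. The order of these low values turned when the longest inter region of each autosome was left out, with 6.30 islands per megabase on chromosome 13 and 5.55 on chromosome 4, while chromosome 19 stayed highest at 46.2. The median over the 22 autosomes was 8.08 islands per megabase with every base counted and 9.42 without those regions. Islands held 2.75% of the bases of chromosome 19, 0.438% of chromosome 4 and 0.393% of chromosome 13. Without the longest inter regions these values were 2.95%, 0.451% and 0.472%.

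The longest autosomal islands lay on chromosome 1 and chromosome 4. On chromosome 1, the island from 228744111 to 228784168 spanned 40058 bases and the island from 161410143 to 161442503 spanned 32361 bases. On chromosome 4, the island from 190986383 to 191013609 spanned 27227 bases. The longest autosomal inter regions ran on chromosome 1 from 121265526 to 142614751 (21349226 bases), on chromosome 15 from 1 to 20100140 and on chromosome 14 from 1 to 19356223. Centromeres and the short arms of some chromosomes are largely unsequenced in hg19, so the length of such inter regions includes assembly gaps. The gene, exon or intron content of the named regions was not assessed.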

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

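The 117 alternatives fixed before the data were examined (pseudocounts, filters on low values, median scaling, other sets of libraries in the fit, the replicate number as a block and leaving out libraries in turn) were not run, because each needs library values assigned to groups. No paired analysis was possible because the library columns carry names that match none of the sample labels. The alternatives that were computed were chosen after seeing the data. Restricting the annotation to the assembled chromosomes left islands at 19.8% of regions, shores at 35.8%, shelves at 30.2% and inter regions at 14.2%, and changed the percent of bases in islands from 0.696% to 0.683%, in shores from 3.25% to 3.18%, in shelves from 2.77% to 2.72% and in inter regions from 93.3% to 93.4%. Leaving out the longest inter region of each autosome raised the islands per megabase from 43.0 to 46.2 on chromosome 19, from 5.39 to 5.55 on chromosome 4 and from 5.25 to 6.30 on chromosome 13, which turned the order of the latter 2. Depth was not assessed.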

Other observations

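The annotation covered 93 sequences, of which 25 were assembled chromosomes. The other sequences held 9 alternate haplotypes, 20 unlocalised contigs and 39 unplaced contigs. The alternate haplotypes carried 4341 regions (2.99% of the total), among them 850 islands. Chromosome 6 accounted for 7 of these haplotypes, with 4153 regions and between 64 and 142 islands on each. An alternate haplotype is another version of a stretch that the assembled chromosome also contains. Coverage in these regions and in their counterparts on chromosome 6 may therefore depend on how reads with several matches were placed. How such reads were placed is not given in the sources used here. Coverage on the alternate haplotypes was not examined.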
